A study of Homo sapiens with 89 samples.

How the data were processed

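The series holds 89 samples of several assays, and 15 RNA-seq samples of polyadenylated RNA had a column in the count tables used here. The other 74 samples, from 4sU sequencing, 3' end sequencing, ChIP-Rx, CUT&RUN and eCLIP, were not analysed here. Per the labels, the authors mapped reads with STAR 2.7.10a to hg19 and counted them per gene with featureCounts 2.0.3. The deposited values of both tables are raw counts per gene, without normalization. The file header of the SHEP table states strand setting 2, a minimum overlap of 10 bases, both ends mapped, no chimeric pairs and Ensembl release 87, with reads that overlap several genes counted for each. The IMR-32 table states no settings, but it has the same gene models. Its strand setting was checked at genes that face a highly expressed gene on the other strand. The antisense density there was 0.0778% of the sense density in SHEP and 0.385% in IMR-32, so both tables were counted by strand. Reads of overlapping genes on a strand can count for each of them, and ribosomal protein genes have pseudogenes, so the values of single ribosomal protein genes are uncertain. Even values made up 65.5 to 77.1% of the counts from 1 to 10, so read ends were counted singly and counts are not independent molecules. Floors cover counting error only and treat counts as independent, so they are too low.

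IMR-32 columns were joined to samples by the doxycycline or solvent name in the column and the replicate number, and SHEP columns by group and replicate number. The 4sU samples of IMR-32 carry similar group labels, so the join of the IMR-32 columns rests on the column names and the fall of EXOSC10. The design text of the series describes cells of other assays, so the identity of the cells compared here rests on the sample labels. Groups follow the sample titles. Comparisons were EXOSC10 depletion against control in IMR-32, and wild type MYCN against no MYCN, 3A against no MYCN and wild type against 3A in SHEP. The labels describe no pairing. Residuals of libraries with the same replicate number correlated at r = -0.03 to 0.14, and those with different numbers at r = -0.13 to 0.06. No block was used in the comparisons. With the replicate number as a block, 5251 genes were called for EXOSC10 depletion, against 4639 without it. In SHEP the block gave 4184 for wild type MYCN, 4794 for 3A and 5414 between the forms, against 3315, 3806 and 4527. Whether replicates of the same number shared a batch was not tested.

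Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr and scaled with TMM, and edgeR's robust quasi-likelihood F test was run with Benjamini-Hochberg adjustment at 0.05, with all SHEP groups in a single fit. The biological coefficient of variation was 0.077 in IMR-32 and 0.108 in SHEP. Of 57905 genes, 17103 in IMR-32 and 14923 in SHEP were tested. Log2 CPM used a prior count of 2. A set of 34 gene lists was tested with two-sided camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a comparison. Leukocyte, epithelial, endothelial and Schwann cell marker lists mostly fell below that number: 2, 2, 2 and 5 of their genes were tested in IMR-32, and 2, 2, 2 and 3 in SHEP. On EXOSC10 depletion 0 of the leukocyte, epithelial and endothelial genes changed. In SHEP the 2 epithelial genes and 1 Schwann cell gene fell with wild type MYCN and were lower than with 3A, 1 endothelial gene fell with 3A, and 1 leukocyte gene was higher with wild type than with 3A.

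The lists, the comparisons, the tests and the rule for named genes were chosen before the data were examined. The rule names EXOSC10 and MYCN, the 8 largest rises and falls with a symbol, adjusted p under 0.05, mean log2 CPM of at least 3 and ranges that do not overlap, and 3 members with the smallest p of each called list. All called members of the nuclear exosome list and of the MYC network list are named by it too. Of the MYC network genes, 4 rose and 6 fell of 20 on EXOSC10 depletion, with camera adjusted p = 0.187. The counts were 1 and 4 of 18 with wild type MYCN, 1 and 3 of 18 with 3A, and 5 and 2 of 18 between the forms. Many of these calls were lost when a single library was left out, which also leaves fewer libraries for the test. On EXOSC10 depletion, MLX, MLXIP, MGA, FBXW7, MYCL and AURKA lost their call without some of the 6 libraries, each of which cost at least 1 of them (edgeR adjusted p = 0.056 to 0.251), and MLX alone of the 4 rises was called without depleted replicate 3. MXD1, the rise with wild type MYCN, was not called with library totals (0.0659), without any replicate lacking MYCN or without wild type replicate 2 (0.0539 to 0.132). The fall of MXD3 with wild type MYCN was lost without no MYCN replicate 2 or 3 or wild type replicate 1 (0.0502 to 0.111), and that of TRRAP with 3A without no MYCN replicate 1 (0.0887) or 3A replicate 3 (0.0703). Between the forms MYC, MXD1, SIN3A and HUWE1 lost their call without some libraries, and each library but wild type replicate 3 cost at least 1 of them (0.072 to 0.226). The genes common to all doxycycline arms were named after their values were seen. Some genes that the rule names are not reported here.

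The test was checked on simulated data with libraries of these depths and this spread. Far fewer genes were changed there than were called in the real data, with 157 to 167 calls per simulated comparison against 3315 to 4639. The recovery rates therefore do not carry over directly to the real comparisons. Of genes changed 1.5-fold, 61.2% were recovered in IMR-32 and 52.2 to 56.1% in the SHEP comparisons. Of genes changed 2-fold, 89.1% were recovered in IMR-32 and 77.6 to 83.1% in SHEP, with 8 to 11 false calls per comparison. Between replicates, the chi-square per degree of freedom was 4.05 to 19.4, and no pair of libraries was a duplicate.

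Alternatives tried were size factors of the DESeq2 type, library totals, no filter, a stricter filter of 1 CPM in 3 libraries, DESeq2, limma-voom, the replicate number as a block, a fit of the compared groups alone, camera with an estimated correlation, fry, other set sizes and leaving out each library. Removal of a gene length trend, thinning of the libraries to equal depth, and leaving out each SHEP library for the sets taken from IMR-32 were added after seeing the data. Correction for GC content was not run because it needs a genome sequence.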

Results

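RNA sequencing of polyadenylated RNA was compared in 2 human neuroblastoma cell lines. IMR-32, an adrenergic line with amplified MYCN, carried an shRNA against EXOSC10 that doxycycline induces. EXOSC10 is a catalytic 3'-5' exonuclease subunit of the nuclear RNA exosome, and MYCN is a transcription factor of the MYC family. In IMR-32, 3 control libraries without doxycycline and 3 libraries with the shRNA and 1 µg/ml doxycycline held 16394148 to 26193478 counts each. SHEP, a mesenchymal line without MYCN amplification, had 3 libraries labelled as lacking MYCN, 3 with wild type MYCN and 3 with MYCN 3A. The labels describe 3A as a triple mutant deficient in RNA binding. The 9 SHEP libraries held 11638859 to 15353505 counts each, and both MYCN forms had 1 µg/ml doxycycline while the libraries without MYCN had none. Tests covered 17103 genes in IMR-32 and 14923 in SHEP. Replicate labels do not say whether the libraries came from separate cultures, so each p measures the spread between these samples. Levels below are CPM, counts scaled to library size, with TMM factors and as mean ± SD, and changes are log2 fold changes with their SE. Each named change passed edgeR's test in groups whose ranges did not overlap, 3 libraries against 3, except that of EXOSC10 with wild type MYCN.

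Depletion of EXOSC10 in IMR-32 asks which transcripts depend on the nuclear exosome. The transcripts of the integrated stress response, the program that ATF4 runs when amino acids are short, and of ribosomal proteins fell nearly throughout, and those of adrenergic identity fell more often than they rose. These list calls were lost with an estimated correlation (adjusted p = 0.124, adjusted p = 0.133 and adjusted p = 0.124 in camera). CHAC1, which degrades glutathione, SLC7A11, the cystine transporter, and ASNS, the asparagine synthetase, were among the transcripts that fell. NGFR, the low-affinity neurotrophin receptor, PDLIM3, an actin-associated protein, and the basement membrane collagens COL4A1 and COL4A2 rose. MYCN itself fell along with EXOSC10.

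EXOSC10 (ENSG00000171824, chromosome 1, 11126675 to 11159938, hg19) went from 68.6 ± 5.48 CPM in the controls to 47.3 ± 1.54 CPM in the depleted libraries (n = 3 each). It fell by 31.1% (log2 fold change -0.54, SE 0.08, adjusted p = 2.3e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MYCN (ENSG00000134323, chromosome 2, 16080686 to 16087129) went from 1100 ± 15.3 to 599 ± 5.47 CPM, a log2 fold change of -0.87 (SE 0.04, adjusted p = 7.5e-30 in the same edgeR test). Among the transcripts that rose, PDLIM3 changed by 4.17 (SE 0.09) and NGFR by 4.05 (SE 0.07). The lipid carrier APOE rose by 2.78 (SE 0.09) and the growth factor IGF2 by 2.71 (SE 0.10). Among the transcripts that fell, CHAC1 changed by -2.61 (SE 0.12), SLC7A11 by -2.19 (SE 0.07) and ATF5, a stress-induced transcription factor, by -2.13 (SE 0.08). DLK1, a Notch pathway ligand, changed by -2.42 (SE 0.07) and NHLH1, a neuronal helix-loop-helix factor, by -2.16 (SE 0.08). All of these changes except that of EXOSC10 had adjusted p of at most 2.9e-28 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the ranges of the 2 groups did not overlap in any of them, EXOSC10 included.

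**Figure D1:**
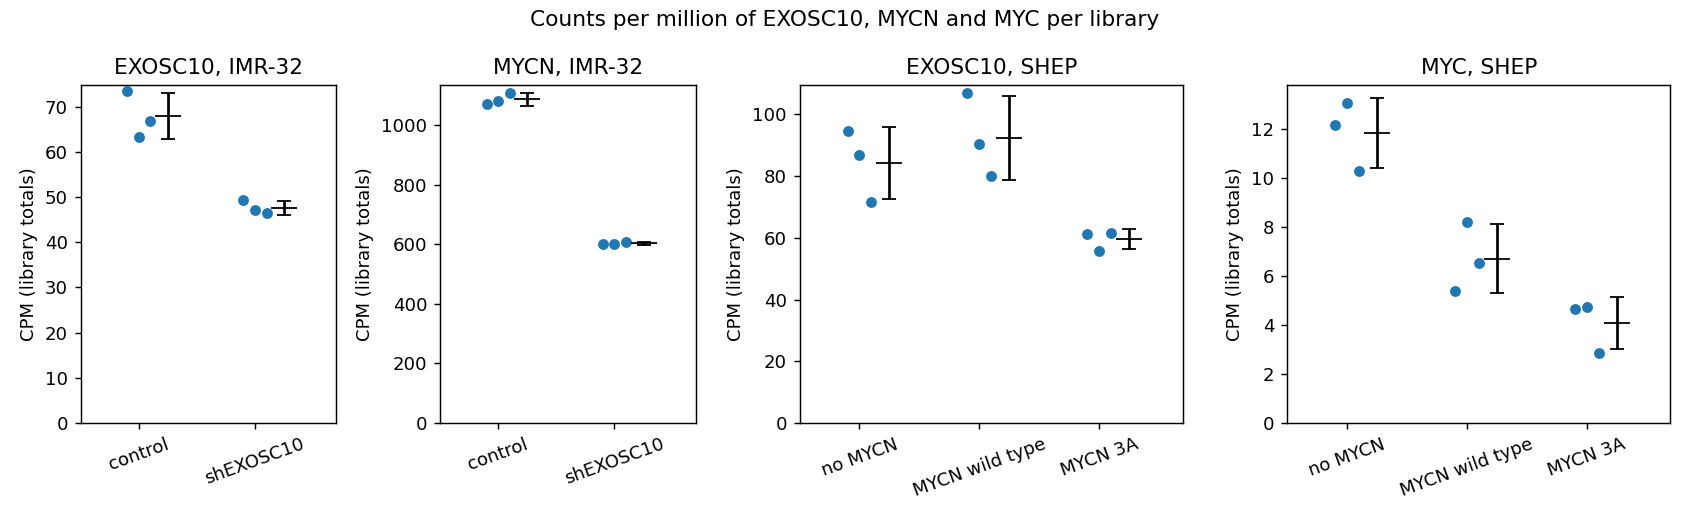
CPM by library totals for EXOSC10 and MYCN in IMR-32 and for EXOSC10 and MYC in SHEP, with 1 point per library and a bar for the group mean ± SD (n = 3). EXOSC10 fell from 67.9 to 47.6 CPM and MYCN from 1090 to 603 CPM in IMR-32.

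Of 32 tested genes of the integrated stress response, 29 fell and 0 rose over all genes, with 29 and 0 adjusted over the list alone. Their median was -0.86 (adjusted p = 1.0e-21 in camera, adjusted p = 0.124 with an estimated correlation). ASNS went from 281 ± 3.13 to 86.8 ± 0.448 CPM and DDIT4, an inhibitor of mTORC1, from 242 ± 7.79 to 55.3 ± 3.92 CPM. Among 65 cytosolic ribosomal protein genes, 62 fell and 0 rose, with 63 and 0 adjusted over the list alone and a median of -0.30 (camera adjusted p = 7.3e-21, adjusted p = 0.133 with an estimated correlation). RPL29 changed by -0.75 (SE 0.05) and RPL34 by -0.85 (SE 0.06). Adrenergic neuroblastoma genes fell in 22 and rose in 6 of 39 cases, or 24 and 6 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 1.4e-05, adjusted p = 0.124 with an estimated correlation). The secretory granule protein gene CHGA went from 954 ± 58.6 to 453 ± 14.3 CPM and the transcription factor gene GATA3 from 397 ± 3.47 to 211 ± 2.48 CPM. MYC targets fell in 21 and rose in 2 of 39 cases, or 22 and 2 adjusted over the list alone, with a median of -0.17 (camera adjusted p = 2.9e-04, adjusted p = 0.133 with an estimated correlation). ODC1, the rate-limiting enzyme of polyamine synthesis, changed by -0.80 (SE 0.06). Nuclear encoded genes of oxidative phosphorylation fell in 26 and rose in 1 of 48 cases, or 29 and 1 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 2.4e-05, adjusted p = 0.178 with an estimated correlation). Cholesterol synthesis genes fell in 11 and rose in 4 of 25 cases, or 12 and 4 adjusted over the list alone, and HMGCS1 changed by -0.69 (SE 0.06) while FDFT1 changed by 0.70 (SE 0.05). Their median was -0.19 (camera adjusted p = 0.00719, adjusted p = 0.133 with an estimated correlation).

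Extracellular matrix and adhesion genes went the other way, with 18 that rose and 5 that fell of 32, or 19 and 5 adjusted over the list alone. Their median was 0.32 (camera adjusted p = 1.0e-04, adjusted p = 0.133 with an estimated correlation). Schwann cell and glial markers, NGFR among them, rose in 3 and fell in 1 of 5 cases, with 3 and 1 adjusted over the list alone and a median of 0.42. Camera did not call them (adjusted p = 0.133), while fry, which does not compare with other genes, gave adjusted p = 4.7e-06. COL4A1 went from 156 ± 8.64 to 550 ± 19.4 CPM and COL4A2 from 597 ± 15.9 to 1650 ± 19.9 CPM. p53 targets rose in 17 and fell in 2 of 28 cases, or 18 and 2 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 1.1e-04, adjusted p = 0.148 with an estimated correlation). The death receptor gene TNFRSF10B rose by 0.78 (SE 0.04). The p53 targets that fell were SESN2 at -0.85 (SE 0.07) and PMAIP1 at -1.13 (SE 0.12), of which SESN2 also belongs to the integrated stress response. Antigen presentation genes rose in 3 and fell in 0 of 5 cases, with 3 and 0 adjusted over the list alone, and B2M, the invariant chain of class I molecules, rose by 0.76 (SE 0.05). The other rises, of ERAP1 and TAPBP, lost their calls without control replicate 2 or 3 or any of the depleted replicates (edgeR adjusted p = 0.0636 to 0.123). The median of the list was 0.51 (camera adjusted p = 0.00699, adjusted p = 0.138 with an estimated correlation). Mitochondrially encoded genes rose in 12 and fell in 1 of 37 cases, with 12 and 1 adjusted over the list alone and a median of 0.18 (camera adjusted p = 0.00613, adjusted p = 0.461 with an estimated correlation). They took 7.90 to 8.22% of the counts in depleted libraries and 6.70 to 7.49% in controls, and without control replicate 3 the list had adjusted p = 0.082 in camera.

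The nuclear exosome list, with EXOSC10 itself, fell in 5 and rose in 1 of 26 cases, with 5 and 1 adjusted over the list alone and a median of -0.15 (camera adjusted p = 0.00613, adjusted p = 0.133 with an estimated correlation). NCBP2, a subunit of the cap-binding complex, changed by -0.47 (SE 0.07) and ZCCHC8, a scaffold of an exosome targeting complex, by -0.33 (SE 0.07). TENT4A, a noncanonical poly(A) polymerase, rose by 0.16 (SE 0.06, adjusted p = 0.0306 in edgeR), a call lost without any library but control replicate 3 (adjusted p = 0.058 to 0.133). Lists of annotated noncoding RNA genes, picked by gene symbol from classes that hold known exosome substrates, showed no called shift in this polyadenylated RNA. EXOSC10 fell only in part, so a smaller shift is not excluded. Of 612 antisense and divergent noncoding RNAs, 35 rose and 32 fell, or 24 and 23 adjusted over the list alone. Their median was 0.04 (camera adjusted p = 0.51). Long intergenic noncoding RNAs rose in 13 and fell in 15 of 189 cases, or 13 and 14 adjusted over the list alone. Their median was 0.16 (camera adjusted p = 0.187). Of 124 snoRNA and scaRNA genes, 3 rose and 3 fell, or 1 and 1 adjusted over the list alone. Their median was -0.02 (camera adjusted p = 0.979).

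Over all genes, 2302 were higher and 2337 lower on EXOSC10 depletion, which is 27.1% of the tested genes, and 398 and 194 of them changed at least 2-fold. The groups did not overlap in 38.4% of tested genes, where chance gives 10%. Immediate early, glycolysis and G1/S genes were called lower too (camera adjusted p = 0.0209, 0.0254 and 0.0209, adjusted p = 0.231, 0.332 and 0.461 with an estimated correlation). The first call was lost without depleted replicate 1 (0.0685), the second without control replicate 2 (0.0503) and the third without either (0.0658 and 0.0594). Camera called 14 lists, and 0 of these calls held with an estimated correlation. Among the lost calls were lists with an estimated correlation below the preset 0.01. It was -0.013 for nuclear exosome, -0.014 for cholesterol synthesis, -0.133 for antigen presentation and 0.005 for adrenergic genes. Correlation between genes does not account for the loss in these lists. A call lost with an estimated correlation therefore does not by itself show that the genes of a list are correlated. The depleted libraries had doxycycline and the controls had none, so both differ together in this comparison.

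Wild type MYCN against no MYCN in SHEP asks what MYCN expression changes in cells without it. MYC targets and ribosome biogenesis genes, the classical growth program of the MYC family, mostly rose, as did most NF-kB targets and 13 of 26 immediate early genes. BIRC3, an inhibitor of apoptosis, TNFAIP3, a feedback inhibitor of NF-kB, and the chemokine CXCL12 rose. The fibrillar collagens COL1A1, COL1A2 and COL5A1 and the keratin KRT8 fell.

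ESM1, an endothelial proteoglycan, went from 2.44 ± 0.266 to 50.1 ± 1.12 CPM (n = 3 each), a log2 fold change of 4.35 (SE 0.17, adjusted p = 1.5e-14 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). BIRC3 (chromosome 11, 102188215 to 102210134) rose by 2.30 (SE 0.13), CXCL12 by 2.20 (SE 0.15) and the guidance factor SLIT2 by 2.10 (SE 0.14). HAS2, a hyaluronan synthase, rose by 2.30 (SE 0.18) and TRIM55, a muscle ubiquitin ligase, by 2.03 (SE 0.09). TES, a focal adhesion protein, changed by -2.47 (SE 0.16) and KRT8 by -1.86 (SE 0.11). COL1A1 (chromosome 17, 48260650 to 48278993) went from 1520 ± 79.4 to 435 ± 56.8 CPM, and COL5A1 changed by -1.75 (SE 0.12). MYC, the paralog that SHEP expresses, went from 11.4 ± 1.31 to 6.80 ± 1.51 CPM, a change of -0.75 (SE 0.21, adjusted p = 0.0115 in the edgeR test). That call was lost when some single libraries were left out. Without wild type replicate 1 the edgeR adjusted p was 0.0506 and without no MYCN replicate 2 it was 0.0608, within a range of 0.00455 to 0.0608 over the alternatives. EXOSC10 was at 93.2 ± 11.6 against 81.1 ± 10.5 CPM, a difference of 0.20 (SE 0.11) that did not pass the edgeR test (adjusted p = 0.195).

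MYC targets rose in 27 and fell in 0 of 39 cases, or 28 and 0 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 2.4e-11, adjusted p = 0.0495 with an estimated correlation). ODC1 went from 711 ± 12.8 to 1320 ± 110 CPM and SLC19A1, a folate transporter, rose by 0.82 (SE 0.10). Ribosome biogenesis genes rose in 30 and fell in 1 of 48 cases, or 35 and 1 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 7.6e-12, adjusted p = 0.0375 with an estimated correlation). RRP9, a subunit of the U3 snoRNP, rose by 0.86 (SE 0.09). NF-kB targets rose in 11 and fell in 1 of 15 cases, or 11 and 2 adjusted over the list alone, with a median of 0.88 (camera adjusted p = 1.4e-06, adjusted p = 0.0375 with an estimated correlation). TNFAIP3 rose by 1.83 (SE 0.17) and the signalling adaptor TRAF1 by 1.52 (SE 0.17). Immediate early genes rose in 13 and fell in 1 of 26 cases, or 14 and 1 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 1.2e-06, adjusted p = 0.0375 with an estimated correlation). FOSL1, an AP-1 subunit, went from 146 ± 5.39 to 374 ± 8.47 CPM. The member that fell was MYC.

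Integrated stress response genes rose in 15 and fell in 2 of 30 cases, or 16 and 2 adjusted over the list alone, with a median of 0.35 (camera adjusted p = 3.2e-05, adjusted p = 0.123 with an estimated correlation). SLC7A5, an amino acid transporter, rose by 0.97 (SE 0.08) and PPP1R15A, a regulator of the phosphatase of eIF2 alpha, by 1.23 (SE 0.11). Extracellular matrix and adhesion genes fell in 19 and rose in 2 of 40 cases, or 19 and 3 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 4.3e-05, adjusted p = 0.293 with an estimated correlation). SPARC, a matrix glycoprotein, changed by -0.84 (SE 0.08). Antigen presentation genes rose in 7 and fell in 0 of 15 cases, with 7 and 0 adjusted over the list alone and a median of 0.42 (camera adjusted p = 0.00235, adjusted p = 0.139 with an estimated correlation). PSMB8, an immunoproteasome subunit, rose by 1.14 (SE 0.16). Glycolysis genes rose in 11 and fell in 2 of 23 cases, with 11 and 2 adjusted over the list alone and a median of 0.21 (camera adjusted p = 6.4e-04, adjusted p = 0.123 with an estimated correlation). The nuclear exosome list rose in 7 and fell in 0 of 26 cases, or 9 and 0 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00232, adjusted p = 0.0584 with an estimated correlation). ZC3H18, which links the cap-binding complex to the exosome, rose by 0.58 (SE 0.10) and the exosome core subunit gene EXOSC5 by 0.55 (SE 0.11). With library totals, 3 of the 26 were called higher. EXOSC1, EXOSC7, MPHOSPH6, RBM7 and ZCCHC7 each lost their call without some of the 6 libraries, and each library cost at least 1 of them (edgeR adjusted p = 0.0507 to 0.149). Mitosis genes fell in 9 (14 with library totals) and rose in 1 of 36 cases, or 13 and 1 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.00656, adjusted p = 0.204 with an estimated correlation).

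Over all genes, 1634 were higher and 1681 lower with wild type MYCN, which is 22.2% of the tested genes, and 200 and 434 of them changed at least 2-fold. The groups did not overlap in 37.5% of tested genes, where chance gives 10%. Splicing factor, polyamine and nucleotide synthesis, G1/S and ribosomal protein genes were called higher too (camera adjusted p = 6.4e-04, 8.7e-04, 0.00488 and 0.00103, adjusted p = 0.151, 0.151, 0.20 and 0.721 with an estimated correlation), the last of them not without wild type replicate 3 (0.211). Camera called 14 lists, and the 4 calls that held with an estimated correlation were MYC targets, ribosome biogenesis, NF-kB targets and immediate early genes. Without wild type replicate 2 the genes that were lower numbered 1064. Scaling by library totals moved the median of all tested genes from 0.00 to -0.07 and gave 1163 genes higher and 2147 lower.

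MYCN 3A against no MYCN asks what a MYCN deficient in RNA binding still changes. MYC targets, ribosome biogenesis genes, ribosomal protein genes and the nuclear genes of oxidative phosphorylation mostly rose with 3A, and extracellular matrix and mitosis genes mostly fell. These list calls were lost with an estimated correlation, with adjusted p of 0.0519, 0.0519, 0.327 and 0.30 for those that rose and 0.22 and 0.171 for those that fell in camera. PPIF, the mitochondrial cyclophilin, and NPM1, the nucleolar histone chaperone, rose. FN1, fibronectin, and CAV1, the coat protein of caveolae, fell.

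TRIM55 went from 47.7 ± 3.65 to 190 ± 3.77 CPM (n = 3 each), a log2 fold change of 1.99 (SE 0.09, adjusted p = 7.3e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). PPIF rose by 1.45 (SE 0.09) and the fatty acid binding protein gene FABP5 by 1.28 (SE 0.13). ADGRG1, an adhesion receptor, changed by -1.93 (SE 0.22), the large scaffold protein gene AHNAK2 by -1.56 (SE 0.15) and COL5A1 by -1.21 (SE 0.12). MYC changed by -1.44 (SE 0.22, adjusted p = 9.8e-05 in the edgeR test), from 11.4 ± 1.31 to 4.20 ± 1.04 CPM. EXOSC10 went from 81.1 ± 10.5 to 61.5 ± 4.02 CPM, a change of -0.40 (SE 0.11, adjusted p = 0.00954 in the edgeR test). That change in EXOSC10 was not called without no MYCN replicate 1 (-0.32, adjusted p = 0.0787) or without 3A replicate 2 (-0.35, adjusted p = 0.0565 in edgeR), and the adjusted p ranged from 0.00155 to 0.0787 over the alternatives.

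MYC targets rose in 29 and fell in 0 of 39 cases, with 29 and 0 adjusted over the list alone and a median of 0.50 (camera adjusted p = 8.4e-15, adjusted p = 0.0519 with an estimated correlation). NPM1 went from 1840 ± 62.7 to 3240 ± 128 CPM. Ribosome biogenesis genes rose in 31 and fell in 0 of 48 cases, or 35 and 0 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 6.1e-14, adjusted p = 0.0519 with an estimated correlation). RRP9 rose by 1.00 (SE 0.09). Cytosolic ribosomal protein genes rose in 57 and fell in 0 of 65 cases, or 64 and 0 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 5.4e-18, adjusted p = 0.327 with an estimated correlation). RPL24 rose by 0.63 (SE 0.10). Oxidative phosphorylation genes rose in 38 and fell in 1 of 48 cases, or 40 and 1 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 7.0e-14, adjusted p = 0.30 with an estimated correlation). The complex I subunit gene NDUFS5 rose by 0.75 (SE 0.10) and the ATP synthase subunit gene ATP5F1D by 0.80 (SE 0.11). Hosts of snoRNAs rose in 15 (9 with library totals) and fell in 1 of 30 cases, or 19 and 2 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 5.6e-06, adjusted p = 0.30 with an estimated correlation). Gene length moved with these groups: the fold change correlated with exonic length across genes (Spearman -0.34, genes not being independent replicates), with a median of 0.19 in the shortest and -0.21 in the longest length class. With the length trend removed, the medians were 0.45 for MYC targets, 0.36 for ribosome biogenesis, 0.34 for ribosomal protein, 0.36 for oxidative phosphorylation and 0.27 for host genes, and camera still called all 5 lists at the preset correlation.

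Extracellular matrix and adhesion genes fell in 29 and rose in 1 of 40 cases, or 30 and 1 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 1.1e-12, adjusted p = 0.22 with an estimated correlation). COL1A1 went from 1520 ± 79.4 to 820 ± 72.2 CPM. Mesenchymal neuroblastoma genes fell in 17 and rose in 4 of 45 cases, or 19 and 4 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.00666, adjusted p = 0.30 with an estimated correlation). FN1 went from 544 ± 63.1 to 273 ± 18.1 CPM, and CAV1 changed by -0.53 (SE 0.09). Mitosis genes fell in 20 and rose in 2 of 36 cases, with 20 and 2 adjusted over the list alone and a median of -0.27 (camera adjusted p = 6.7e-05, adjusted p = 0.171 with an estimated correlation). ANLN, a cytokinesis scaffold, changed by -0.71 (SE 0.11). The nuclear exosome list rose in 8 and fell in 2 of 26 cases, or 11 and 3 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.00449, adjusted p = 0.125 with an estimated correlation). The core subunit genes EXOSC7 and EXOSC9 rose by 0.72 (SE 0.12) and 0.45 (SE 0.08), while EXOSC10 fell. EXOSC2, EXOSC8, MPHOSPH6 and TENT4A each lost their call without some of the 6 libraries, and each library cost at least 1 of them (edgeR adjusted p = 0.0532 to 0.146). NF-kB targets rose in 1 and fell in 1 of 15 cases, or 3 and 3 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.831).

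Over all genes, 1893 were higher and 1913 lower with 3A, which is 25.5% of the tested genes, and 59 and 168 of them changed at least 2-fold. The groups did not overlap in 41.3% of tested genes, where chance gives 10%. Polyamine and nucleotide synthesis, splicing factor, G1/S, heat shock and integrated stress response genes were called higher too (camera adjusted p = 3.0e-05, 0.00121, 0.00449, 0.00449 and 0.00835, adjusted p = 0.16, 0.227, 0.251, 0.227 and 0.30 with an estimated correlation). Camera called 14 lists, and 0 of these calls held with an estimated correlation. Without no MYCN replicate 1 the counts were 1144 higher and 1022 lower, without no MYCN replicate 2 the lower count was 1227, and without 3A replicate 3 it was 1235. Scaling by library totals moved the median of all tested genes from -0.04 to -0.14 and gave 1232 genes higher and 2928 lower, so the list medians are read relative to that shift.

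Wild type MYCN against 3A compares libraries that both had doxycycline, although the MYCN levels and starting lines behind them are not known to match. Most NF-kB targets and immediate early genes were higher with wild type MYCN, and so were part of the mesenchymal, interferon response and antigen presentation genes. These list calls were lost with an estimated correlation (camera adjusted p = 0.0669, 0.0669, 0.335, 0.181 and 0.329). Part of the ribosomal protein genes and most oxidative phosphorylation genes were lower with wild type than with 3A, calls that were lost as well (adjusted p = 0.698 and 0.576 with an estimated correlation). TRAF1 and TNFAIP3 of the NF-kB pathway and OAS3, an antiviral oligoadenylate synthetase, were among the transcripts furthest above 3A. TES, KRT8 and HES1, a repressor downstream of Notch, were among those furthest below.

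ESM1 was at 50.1 ± 1.12 CPM with wild type and 3.55 ± 0.582 CPM with 3A (n = 3 each), a difference of 3.82 (SE 0.16, adjusted p = 1.4e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). OAS3 differed by 2.01 (SE 0.17), SLIT2 by 2.37 (SE 0.15) and CXCL12 by 2.32 (SE 0.16). TES differed by -2.42 (SE 0.16), KRT8 by -1.65 (SE 0.11), HES1 by -1.31 (SE 0.14) and DNAJC15, a mitochondrial cochaperone, by -1.53 (SE 0.15). EXOSC10 was at 93.2 ± 11.6 against 61.5 ± 4.02 CPM, a difference of 0.60 (SE 0.11, adjusted p = 2.5e-04 in the edgeR test). MYC differed by 0.69 (SE 0.23, adjusted p = 0.0245 in the edgeR test), and this was not called without wild type replicate 2 (adjusted p = 0.139) or without 3A replicate 3 (adjusted p = 0.134), within a range of 0.00987 to 0.139 over the alternatives.

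NF-kB targets were higher in 10 and lower in 1 of 15 cases, with 10 and 1 adjusted over the list alone and a median of 1.01 (camera adjusted p = 3.8e-06, adjusted p = 0.0669 with an estimated correlation). BIRC3 was at 67.4 ± 1.76 against 17.8 ± 2.26 CPM. Immediate early genes were higher in 16 and lower in 0 of 26 cases, or 18 and 0 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 2.7e-07, adjusted p = 0.0669 with an estimated correlation). FOSL1 differed by 1.11 (SE 0.08) and CCN1, a matricellular target of YAP, by 0.92 (SE 0.08). Mesenchymal neuroblastoma genes were higher in 22 and lower in 6 of 45 cases, or 23 and 6 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.00218, adjusted p = 0.335 with an estimated correlation). Interferon response genes were higher in 9 and lower in 1 of 20 cases, or 10 and 1 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00713, adjusted p = 0.181 with an estimated correlation). STAT2 differed by 0.82 (SE 0.16). Antigen presentation genes were higher in 7 and lower in 2 of 15 cases, with 7 and 2 adjusted over the list alone and a median of 0.40 (camera adjusted p = 0.0203, adjusted p = 0.329 with an estimated correlation). The transporter gene TAP1 differed by 0.96 (SE 0.17) and the peptide-trimming enzyme gene ERAP1 by 0.97 (SE 0.13).

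Oxidative phosphorylation genes were lower in 31 and higher in 0 of 48 cases, or 35 and 1 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 1.1e-07, adjusted p = 0.576 with an estimated correlation). UQCRFS1, the Rieske subunit of complex III, differed by -0.58 (SE 0.09). Cytosolic ribosomal protein genes were lower in 29 and higher in 0 of 65 cases, or 32 and 0 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 2.7e-07, adjusted p = 0.698 with an estimated correlation). RPS29 differed by -0.67 (SE 0.11). The fold change correlated with exonic length across genes here too (Spearman 0.27), with a median of -0.17 in the shortest and 0.18 in the longest length class. With the length trend removed, the medians were -0.25 for oxidative phosphorylation and -0.21 for ribosomal protein genes, still called at the preset correlation. MYC targets were higher in 7 and lower in 13 of 39 cases, with 7 and 13 adjusted over the list alone, a median of -0.05 and camera adjusted p = 0.425. Ribosome biogenesis genes were higher in 7 and lower in 11 of 48 cases, or 8 and 12 adjusted over the list alone, with a median of 0.00 and camera adjusted p = 0.81. The nuclear exosome list was higher in 3 and lower in 3 of 26 cases, with 3 and 3 adjusted over the list alone and camera adjusted p = 0.98. ZC3H18 differed by 0.67 (SE 0.10) and EXOSC10 by 0.60 (SE 0.11), whereas EXOSC4 differed by -0.81 (SE 0.15).

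Over all genes, 2359 were higher and 2168 lower with wild type MYCN than with 3A, which is 30.3% of the tested genes, and 349 and 287 of them differed at least 2-fold. The groups did not overlap in 40.4% of tested genes, where chance gives 10%. Glycolysis, integrated stress response and histone genes were called higher and snoRNA hosts lower (camera adjusted p = 0.0271, 0.0364, 0.0203 and 0.0271, adjusted p = 0.352, 0.498, 0.329 and 0.698 with an estimated correlation). These calls were lost without wild type replicate 3 for the first 3 lists (0.0574, 0.127 and 0.0574) and without wild type replicate 1 for the hosts (0.16). Without 3A replicate 1 the glycolysis and stress response calls were lost (0.104 for each), and without 3A replicate 2 the latter (0.0672). With the gene length trend removed, the medians of glycolysis genes and snoRNA hosts went from 0.21 to 0.12 and from -0.19 to -0.12, and both calls were lost (0.106 and 0.0518). Camera called 11 lists, and 0 of these calls held with an estimated correlation.

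**Figure D2:**
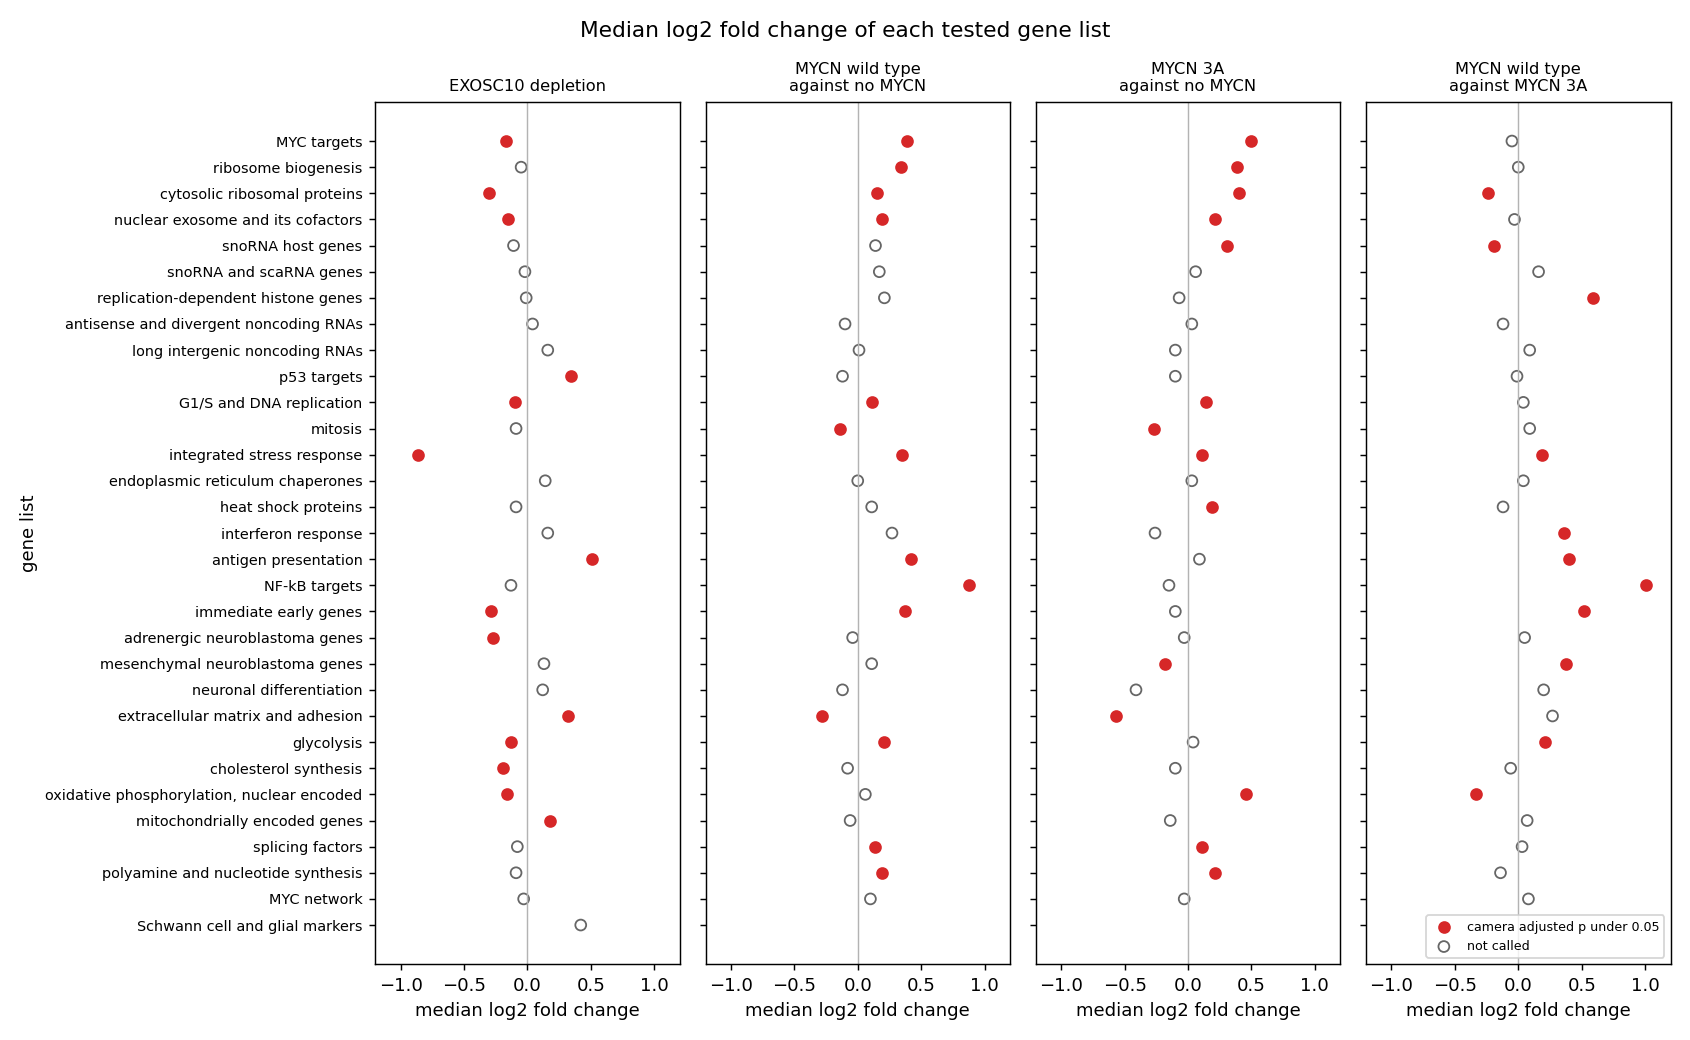
Median log2 fold change (horizontal axis) of each gene list with at least 5 tested genes (vertical axis) in the 4 comparisons, filled where camera called the list at the preset correlation and open where it did not. NF-kB targets lay at 0.88 with wild type MYCN and -0.15 with 3A, and the integrated stress response at -0.86 on EXOSC10 depletion.

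The MYCN gene itself stayed near 0 counts in all 9 SHEP libraries, those labelled with a MYCN construct included. It was at 0.087 ± 0.151 CPM of library totals in the libraries without MYCN, 0.046 ± 0.0797 CPM with wild type and 0.243 ± 0.421 CPM with 3A (n = 3 each), and was too low to be tested. At these depths a count of 0 allows up to 0.195 to 0.258 CPM for counting error only, if the 3 counts behind this bound were independent. Read ends were counted singly, so the true bound is higher. MYCN in IMR-32 controls, measured the same way, was at 1090 ± 20.8 CPM.

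The effects of both MYCN forms were compared gene by gene against the libraries they share. Of the genes higher with wild type MYCN, 596 were also higher with 3A, such as TRIM55, ODC1 and RRP9, where independence would give 207.3. Of the genes lower with wild type, 522 were also lower with 3A, such as COL1A1, COL5A1 and ADGRG1, where independence would give 215.5. Across 14923 genes, which are not independent replicates, the effects correlated with Pearson r = 0.36 and Spearman rho = 0.37, and their covariance was 0.0887. In 20 simulated draws without changed genes, with simulated controls shared by both groups, r was 0.502 and the covariance 0.0308. The draws gave 0.7 calls on average and 0.0 genes called in both comparisons. They therefore cannot show how far shared controls raise the correlation or the overlap where many genes changed. The real controls were too few to split, so part of the excess overlap can come from sharing them.

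**Figure D3:**
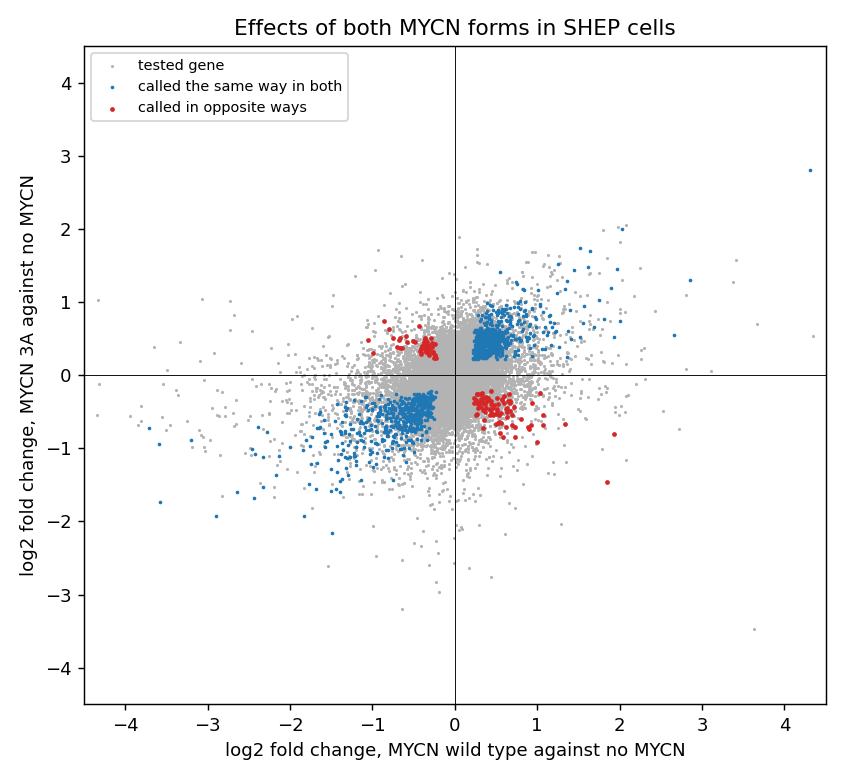
Log2 fold change with wild type MYCN (horizontal axis) against that with 3A (vertical axis), both against no MYCN, for each gene tested in SHEP, with 12 genes outside the axes. Blue points are the 596 genes higher and 522 lower in both, and red points are the 85 and 50 genes called in opposite ways.

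Gene sets from each line were tested in the other in a family of 8 camera tests. The 200 genes that rose most clearly on EXOSC10 depletion had a median of -0.26 with 3A, with 15 that rose and 60 that fell (camera adjusted p = 4.9e-04 over the 8 tests, adjusted p = 0.174 with an estimated correlation). That set had a median of -0.08 with wild type MYCN (camera adjusted p = 0.0986). The 200 genes that fell most clearly on EXOSC10 depletion had a median of 0.09 with wild type (camera adjusted p = 0.0715) and 0.04 with 3A (adjusted p = 0.226). The 200 genes most clearly higher with wild type MYCN had a median of -0.06 on EXOSC10 depletion (camera adjusted p = 0.0528), and those most clearly lower had 0.09 (adjusted p = 0.0958). Between wild type and 3A the EXOSC10 sets had medians of 0.10 (camera adjusted p = 0.224) and 0.08 (adjusted p = 0.274). Thus 1 of the 8 tests passed at the preset correlation and 0 with an estimated one.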

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

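The count of opposite signs, the count with the gene length trend removed and the counts at equal depth were tests chosen after the numbers of genes were seen. Among the groups that differed between wild type MYCN and 3A were genes of NF-kB signalling, which answer inflammatory and survival signals, and genes of oxidative phosphorylation, the mitochondrial energy pathway. The median of NF-kB targets was 1.01 higher with wild type MYCN than with 3A, a difference tested directly (camera adjusted p = 3.8e-06, adjusted p = 0.0669 with an estimated correlation). The median of oxidative phosphorylation genes differed by -0.33 in the same test (camera adjusted p = 1.1e-07, adjusted p = 0.576 with an estimated correlation). EXOSC10, an exonuclease of the nuclear exosome, differed by 0.60 (SE 0.11, adjusted p = 2.5e-04 in edgeR's quasi-likelihood test). In 85 genes the transcript was called higher in wild type and lower in 3A libraries than in those without MYCN, against 596 called higher in both. Their difference between the forms passed the test too, but calls in opposite directions against the same libraries make that nearly certain. Examples were DIO2, which activates thyroid hormone (1.94 and -0.80), and OAS3 (1.34 and -0.67). In 50 genes it was the reverse, such as DNAJC15 (-1.05 and 0.48), against 522 called lower in both.

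More genes differed between wild type MYCN and 3A, 4527, than between either form and no MYCN, 3315 and 3806, but this order was lost with only the compared groups in the fit (3966 between the forms, 3330 with wild type and 4263 with 3A) and without wild type replicate 1 (3261 between the forms and 3458 with wild type). If 3A only kept part of the wild type effect, the 3A effect and the difference between the forms would have the same sign. Of 1991 genes called in both, 1840 had opposite signs, where the thresholds of both tests allow 417 false calls. Both tests use the 3A libraries, with opposite sign, so a shift of these libraries from any cause gives opposite signs. Opposite signs also arise where 3A moved a gene the same way as wild type but further. Of the 4527 genes, 3A lay between no MYCN and wild type in 842 and beyond wild type in 846. It lay on the other side of no MYCN in 2839, or 62.7%, against 37.3% of all tested genes. These positions use all estimates, called or not, and picking genes by the difference between the forms favours opposite sides. Genes called in opposite ways against no MYCN numbered 85 and 50. The signs therefore do not decide whether 3A kept part of the wild type effect. A gene length trend is argued against as the whole cause in the fit of all groups, where 4267 genes differed between the forms with the trend removed, against 3824 and 3422 for wild type and 3A, and at equal depth the counts were 4407, 3177 and 3728. That the constructs sit in cell lines that may have differed before induction stays open, because the labels name 1 group without doxycycline, and it cannot be told apart from an effect of the mutation. Unequal levels of the MYCN forms stay open as well, because the level of each form in SHEP is unknown. An effect of the lost RNA binding is the biological explanation that the design names, and it stays untested.

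The 6 libraries of each comparison split in 10 ways, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes, and the real counts were 4639 for EXOSC10 depletion, 3315 for wild type, 3806 for 3A and 4527 between the forms, with 0 genes in the highest of the other splits.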

How the results depend on the processing

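Removal of the gene length trend, thinning to equal depth, and leaving out SHEP libraries for the EXOSC10 sets were tests chosen after the results were seen. No result that had passed its test changed direction under the alternatives run. Some lists that were not called changed sign, such as oxidative phosphorylation with wild type MYCN (0.06, and -0.01 with library totals) and MYC network genes with 3A (-0.03, and 0.12 with the length trend removed). DESeq2, limma-voom, size factors of the DESeq2 type, the low count filters, equal depth and the length trend left every count of genes within 1.5 times, and thinning gave 4379 calls for EXOSC10 depletion. Similar counts can hold other genes. With the length trend removed, 2683 of the 3806 calls with 3A and 3487 of the 4527 between the forms were kept. For wild type MYCN 3301 of 3315 were kept, and for EXOSC10 depletion 4331 of 4639.

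With an estimated correlation camera called 0 lists for EXOSC10 depletion, 4 for wild type MYCN, 0 for 3A and 0 between the forms. Some calls were lost although the estimated correlation was below the preset 0.01, as for the nuclear exosome list with wild type MYCN (-0.012). Correlation between genes does not account for such losses, so a lost call does not by itself show correlated genes. With library totals 3A had 1232 genes higher and 2928 lower, where the median of all genes also moved down. Leaving out 1 library gave 1064 to 1714 genes lower with wild type, 1144 to 1821 higher and 1022 to 1795 lower with 3A. The lowest values came without wild type replicate 2 for the first and without no MYCN replicate 1 for the others, and the lower genes with 3A also numbered 1227 without no MYCN replicate 2 and 1235 without 3A replicate 3. The cause was not tested.

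The genes higher with wild type MYCN had a median of -0.01 on EXOSC10 depletion with 100 genes, no longer past the threshold. Those lower had 0.06 with 500 genes, 0.09 with an estimated correlation and 0.08 with the replicate block, none past it, and 0.07 to 0.10 without 1 library, past it only without control replicate 1. The genes that rose on EXOSC10 depletion had a median of -0.10 with wild type with 500 genes, past the threshold, and -0.14 to -0.01 without 1 library, past it without no MYCN replicate 3 or wild type replicate 1. With 3A their median of -0.26 was not past it with an estimated correlation, and the genes that fell had 0.07 with 500 genes, past it. Between the forms those that rose had 0.05 to 0.12 without 1 library, past the threshold without wild type replicate 3. These thresholds are unadjusted, and the cause was not tested.

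Of 257 tested values of named genes, 3 lost their call with DESeq2, 2 with limma-voom, 9 with library totals, 7 without a filter and 11 with the length trend removed, and of 1542 values without 1 library, 111 did. Simulated libraries of these depths, with far fewer changed genes than the real data, recovered 77.6 to 89.1% of genes changed 2-fold. Smaller changes in genes of low counts can be missed.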

Other observations

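The tests of the MYCN gene were chosen after its counts were seen, and the genes common to all doxycycline arms were picked after their values were seen. Of the genes higher with both wild type MYCN and 3A, 48 of 567 tested were also higher in the IMR-32 arm with doxycycline. Of those lower with both, 65 of 491 were also lower there. Among all 17103 genes tested in IMR-32, 2302 were higher and 2337 lower, so these overlaps were no larger a share than among all genes. UNC5C, a netrin receptor, was higher by 2.24 on EXOSC10 depletion, 0.79 with wild type MYCN and 1.01 with 3A, and B2M, the invariant chain of class I molecules, by 0.76, 0.40 and 0.26. Among the genes that were lower, TGFB2, a growth factor of the TGF-beta family, changed by -1.41, -0.38 and -0.51, MFAP4, an elastic fiber protein, by -0.84, -2.38 and -0.71, and ADGRG1 by -0.70, -1.83 and -1.93.

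MYCN, the gene that both SHEP constructs are named for, had at most 10 counts in any construct library. That the gene model cannot be counted is argued against by IMR-32, where the smallest MYCN count was 9844. A swap of the group without MYCN with a construct group is argued against by MYC targets such as ODC1, whose median rose by at least 0.39 in both comparisons. That construct reads were not assigned to the reference gene, as a recoded sequence could cause, stays open, because no construct sequence was at hand, so the level of each MYCN form in SHEP is unknown.

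Genes called the same way with wild type MYCN and 3A, such as TRIM55, ODC1 and COL1A1, may reflect doxycycline as well as MYCN, since the libraries without MYCN had none. In the IMR-32 arm with doxycycline, the genes higher in both had a median of -0.12, with 48 called the same way and 164 the opposite way of 567 tested (camera direction down, p = 3.7e-05, p = 0.0527 with an estimated correlation). The genes lower in both had a median of 0.04, with 65 and 132 of 491 (camera direction up, p = 0.0518, p = 0.116 with an estimated correlation). A shared doxycycline response would move these sets the same way, and the medians met what was written beforehand against it, but that prediction left out that MYCN itself fell by 0.87 in that arm. MYC targets fell there in 21 and rose in 2 of 39 cases (camera adjusted p = 2.9e-04, adjusted p = 0.133 with an estimated correlation), which could hide such a response, so doxycycline and MYCN cannot be told apart for these genes.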
